A study of Rattus norvegicus with 6 samples.

How the data were processed

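RNA sequencing was performed on colon tissue cut from the anastomotic site of male Sprague-Dawley rats, an outbred laboratory strain, 2 weeks after surgery. In 3 libraries the bowel ends had been joined by magnetic compression anastomosis (MCA), in which paired magnets press the cut ends together until they fuse, and in 3 control libraries they had been joined by conventional suture. Groups and replicate numbers were taken from the treatment labels, the titles and the descriptions, which call the libraries of a group biological replicates. Per the labels' protocols, RNA was extracted with TRIzol, libraries were made with the NEBNext Ultra RNA kit and sequencing was done on a DNBSEQ-T7 instrument. The labels' protocols also say that the deposited values are a matrix of normalized FPKM (fragments scaled to gene length and to library total), made by the authors from that sequencing. The submitters' processing notes name limma without stating its role. The aligner, the counting program, the genome build, the annotation and the strand setting are not given in the sources used here, so reads shared between near-identical or overlapping genes were left as the authors' counting assigned them.

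The deposited FPKM table held 21417 Ensembl rat gene identifiers, each above 0 in at least 1 library, and no gene symbols. The reference table used here held 47357 rat genes with no Ensembl identifiers, and 0 of the 21417 identifiers matched it. Gene names were therefore not assigned. The 51 gene lists (cell types, matrix, inflammation, epithelium and others) and the 20 genes commonly measured in anastomotic healing that had been fixed before the data were examined are not analysed here. For the same reason no chromosome, exon or gene function is given for any gene. The fixed rule named genes by size of change among those passing the adjusted threshold, filled up with the smallest unadjusted p among genes whose groups did not overlap and whose log2 fold was at least 1 in size. It also asked for gene symbols. In the absence of symbols its fill-up part was applied to identifiers, and 2 genes per direction are given, fewer than the rule set.

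Values had been deposited at full precision, and this allowed the library totals behind them to be recovered. FPKM is a whole number of fragments divided by gene length and library total, so the commonest ratio between 2 libraries among genes under 0.5 FPKM equals the inverse ratio of their totals. Between 361 and 430 genes carried each such ratio. All 21417 genes gave whole fragments in every library for a whole gene length, within 1e-07 of a fragment. A length and its fragments may both lack a common factor. The recovered fragments of the listed genes made up between 99.55% and 99.64% of each recovered library total. The totals are therefore nearly all fragments assigned to listed genes, and fragments sequenced but not counted cannot be seen. On simulated fragments the method returned the exact library totals and 99.1% of the lengths of 1380 genes. No 2 libraries were copies of each other: the lowest chi-square of recovered fragments per gene over the 15 pairs was 52.0, where sampling noise alone gives about 1.

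Because FPKM values are not counts, the main test was run on log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 6 libraries were kept, which left 13591 and removed 7826. Group differences were tested with limma 3.58.1 in R 4.3.3 (linear model without covariates, empirical Bayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over the genes kept and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes, so mean FPKM values are given beside them. Similarity of libraries was measured by Spearman's correlation across genes for the 15 pairs and compared within and between groups over the 10 ways to split the libraries 3 against 3. Measures of whole libraries were compared with two-sided exact permutation tests, for which 3 against 3 cannot give a p below 0.1. Scripts also used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

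The limma procedure was tested on data simulated from its own fitted variances for this comparison, with 200 of 13591 genes changed, over 20 runs. It recovered 2.31% of genes shifted by 1 unit of log2(FPKM + 1), 52.5% of those shifted by 2 units and 81.5% of those shifted by 3. Such a shift is a larger fold in FPKM for low genes. The mean number of false calls per run was 4.80. Shifts went up and down without a lower bound, so low genes shifted down could take values that FPKM cannot. Simulated genes varied independently of each other, which real genes do not. All simulated libraries of a gene also had the same variance. Quality weights estimated for the real libraries ran from 0.290 for MCA replicate 2 to 4.31 for MCA replicate 1.

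The alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a filter at a mean of 5 FPKM, 4 further scalings (median centring, quantile normalization, rescaling to equal total FPKM, and trimmed mean factors with 30% of ratios and 5% of levels trimmed at each end), 3 variance models (no trend, robust, and array weights), the replicate number as a block, and leaving out each library. A pair of alternatives was added after seeing the data: limma-voom on the recovered fragments, and leaving out the 10 most abundant genes with rescaling.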

Results

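The data comprised 6 RNA-seq libraries from rat colonic anastomoses collected 2 weeks after surgery, 3 made by magnetic compression (MCA) and 3 by suture. The question was how gene expression at the healing site differed between the 2 ways of joining the bowel. The library totals recovered from the deposited FPKM values were close to one another. They were 15791079, 14867454 and 15588802 fragments in MCA replicates 1, 2 and 3, and 15558664, 15632524 and 15091682 in suture replicates 1, 2 and 3. The largest total exceeded the smallest by a factor of 1.06. No difference in the totals was detected between the 2 groups (exact permutation test, p = 1), a test that cannot give a p below 0.1 here. The number of genes above 0 was 18352 ± 357 (SD, n = 3) with MCA and 18534 ± 140 (SD, n = 3) with suture. No group difference was detected in it (exact permutation test, p = 0.5).

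A small number of genes supplied a large and variable part of every library. The 7 genes with the highest mean FPKM over the 6 libraries together held 28.0% ± 7.27 (SD, n = 3) of total FPKM in the MCA group and 25.5% ± 10.3 (SD, n = 3) in the suture group. Their share was 19.8%, 30.6% and 33.6% in MCA replicates 1, 2 and 3. It was 18.7%, 37.3% and 20.4% in suture replicates 1, 2 and 3. In fragments, the 7 genes accounted for 17.5% ± 5.46 (SD, n = 3) of the library with MCA and 15.7% ± 6.74 (SD, n = 3) with suture. No group difference was detected in either share (exact permutation test, p = 0.9 for both).

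**Figure D1:**
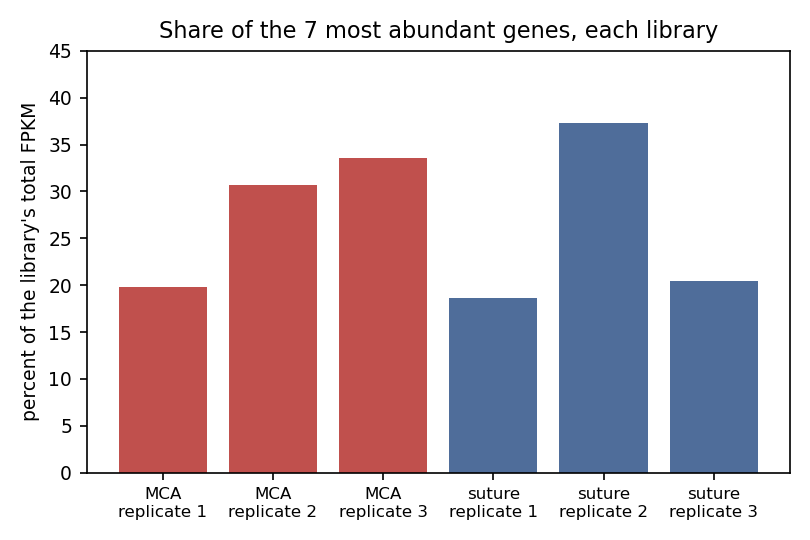
Percent of each library's total FPKM held by the 7 most abundant genes (vertical axis, starting at 0) for the 3 MCA libraries in red and the 3 suture libraries in blue. Shares run from 18.7% in suture replicate 1 to 37.3% in suture replicate 2, and the groups overlap.

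Spearman's correlation across the 13591 genes tested averaged 0.901 within groups and 0.894 between groups, a difference of 0.0061. The difference turned negative without suture replicate 1 (-0.0093), 2 (-0.0064) or 3 (-0.0096), and was 0.029 without MCA replicate 1. Of the 10 splits of the libraries into 3 and 3, 4 gave a difference at least this large (exact permutation p = 0.4, and 0.1 is the smallest this design allows). The MCA libraries resembled each other less, with a mean correlation of 0.872, than the suture libraries did, with 0.930, and this contrast was not tested. It rested on MCA replicate 2, which correlated at 0.867 and 0.809 with MCA replicates 1 and 3, while those correlated at 0.938 with each other. The closest library was often one of the other group. MCA replicate 2 correlated best with suture replicate 2 (0.901), and MCA replicate 1 with suture replicate 3 (0.953). Suture replicate 1 correlated best with MCA replicate 1 (0.948). MCA replicate 3 and suture replicates 2 and 3 were each closest to a library of their own group. MCA replicate 2 had the lowest mean correlation with the other 5 libraries, 0.850, against 0.880 to 0.926 for the rest. The lowest correlation of any pair was 0.804, between MCA replicate 2 and suture replicate 1. The highest was 0.954, between suture replicates 2 and 3. The correlations are across genes, which are not independent replicates.

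The first principal component of log2(FPKM + 1) carried 48.5% of the variance and did not order the libraries by group. MCA replicate 2 scored 79.6 and suture replicate 2 scored 25.1, and the other 4 libraries scored between -39.4 and -6.72 (exact permutation test of the groups, p = 0.8). The second component, with 24.7% of the variance, placed every MCA library above every suture library. MCA scores averaged 24.6 ± 27.9 (SD, n = 3) and suture scores -24.6 ± 6.85 (SD, n = 3). The exact permutation p was 0.1, the smallest possible with 3 against 3, and 0.5 after Benjamini-Hochberg adjustment over the 5 components. MCA replicate 1, at 2.97, lay nearer to the suture libraries than MCA replicate 3, at 56.0.

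**Figure D2:**
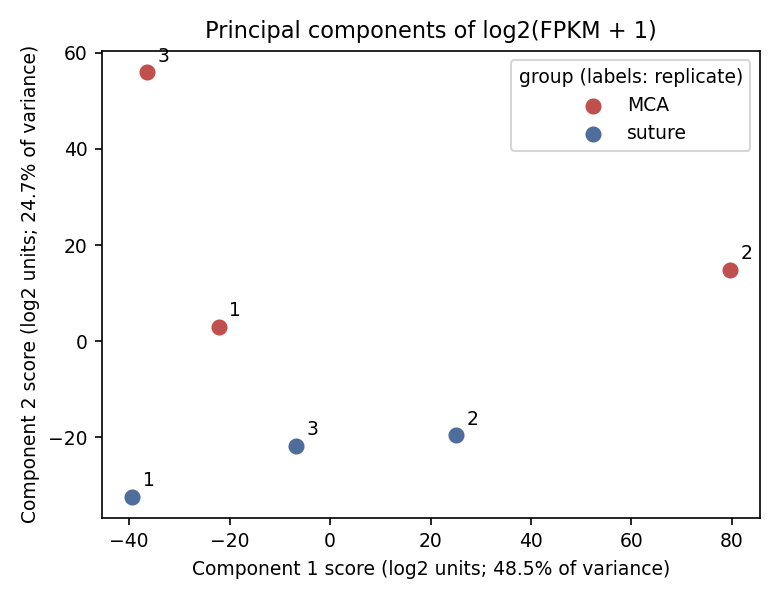
Scores of the 6 libraries on the first (horizontal) and second (vertical) principal components of log2(FPKM + 1), in log2 units, with MCA in red, suture in blue and the replicate number beside each point. MCA replicate 2 lies apart on the first component at 79.6, and the second component parts the groups.

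In the gene-by-gene comparison of MCA with suture, 0 of 13591 genes passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), and the smallest adjusted p was 0.0632. At an unadjusted p under 0.05 limma gave 667 genes, 4.91% of those tested, where 680 are expected by chance alone. These comprised 476 genes with a higher and 191 with a lower mean in the MCA group. With a fold of at least 2 added, 350 genes remained, of which 247 were higher and 103 lower with MCA. Most genes with the smallest p had higher means in the MCA group: this held for the first 20 and for 97 of the first 100. Genes vary together, and this count was not set against other splits of the libraries. The groups did not overlap in 1182 genes, 8.70% of those tested, against 10% expected by chance. Of these, 840 were higher and 342 lower with MCA. On the recovered fragments, limma-voom also gave 0 genes past the adjusted threshold, and 644 at an unadjusted p under 0.05. Array quality weights, estimated from the same libraries, ended the count of 0 and gave 35 genes, 34 of them higher with MCA. These weights were 4.31, 0.290 and 0.871 for MCA replicates 1, 2 and 3, so replicate 1 dominated the MCA mean. They were 0.656, 0.825 and 1.70 for suture replicates 1, 2 and 3. Without MCA replicate 2, limma gave 0 genes past the adjusted threshold and 1065 at an unadjusted p under 0.05, of which 751 were higher and 314 lower with MCA. The excess of higher genes turned without suture replicate 1, which left 328 higher against 335 lower at an unadjusted p under 0.05, and 183 higher against 251 lower with a fold of at least 2 added.

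**Figure D3:**
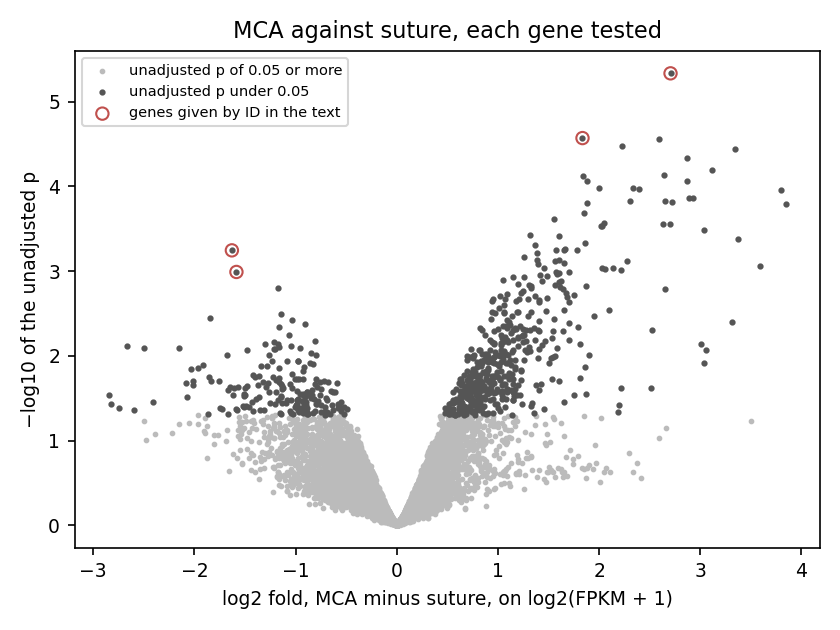
Log2 fold of MCA over suture on log2(FPKM + 1) (horizontal) against −log10 of the unadjusted limma p (vertical) for the 13591 genes tested, with genes under an unadjusted p of 0.05 in dark grey and the 4 genes given by identifier circled. The highest points lie on the side of higher means with MCA, and 0 genes pass the adjusted threshold.

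The deposited table gives Ensembl identifiers without gene symbols, so genes are given by identifier and their functions are not described. Among the genes whose groups did not overlap and that had at least a 2-fold change, the smallest unadjusted p with a higher mean in MCA belonged to ENSRNOG00000024390. Its level was 10.1 ± 1.58 FPKM (SD, n = 3) with MCA and 0.695 ± 0.165 FPKM (SD, n = 3) with suture, a ratio of means of 14.5. Between 381 and 486 fragments stood behind each MCA value and between 25 and 38 behind each suture value. Its log2 fold was 2.71 with a standard error of 0.214 and a limma adjusted p of 0.0632. ENSRNOG00000005214 was next, with 9.31 ± 0.760 FPKM (SD, n = 3) with MCA and 1.88 ± 0.157 FPKM (SD, n = 3) with suture, a ratio of means of 4.94 (277 to 345 and 59 to 69 fragments). Its log2 fold was 1.84 with a standard error of 0.189 and a limma adjusted p of 0.0997. In the other direction, ENSRNOG00000023476 had 0.882 ± 0.491 FPKM (SD, n = 3) with MCA and 4.75 ± 1.00 FPKM (SD, n = 3) with suture, and the suture mean was 5.39 times the MCA mean (21 to 59 and 170 to 255 fragments). Its log2 fold was -1.63 with a standard error of 0.273 and a limma adjusted p of 0.194. ENSRNOG00000003510 had 5.54 ± 1.85 FPKM (SD, n = 3) with MCA and 18.5 ± 4.60 FPKM (SD, n = 3) with suture, and the suture mean was 3.34 times the MCA mean (122 to 242 and 420 to 679 fragments). Its log2 fold was -1.58 with a standard error of 0.294 and a limma adjusted p of 0.247. In the order given, these 4 genes ranked 1, 2, 39 and 55 by unadjusted p among all genes tested. None of them passed the adjusted threshold in this test. All 3 MCA libraries lay on one side of all 3 suture libraries in each, which is how the genes were selected.

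**Figure D4:**
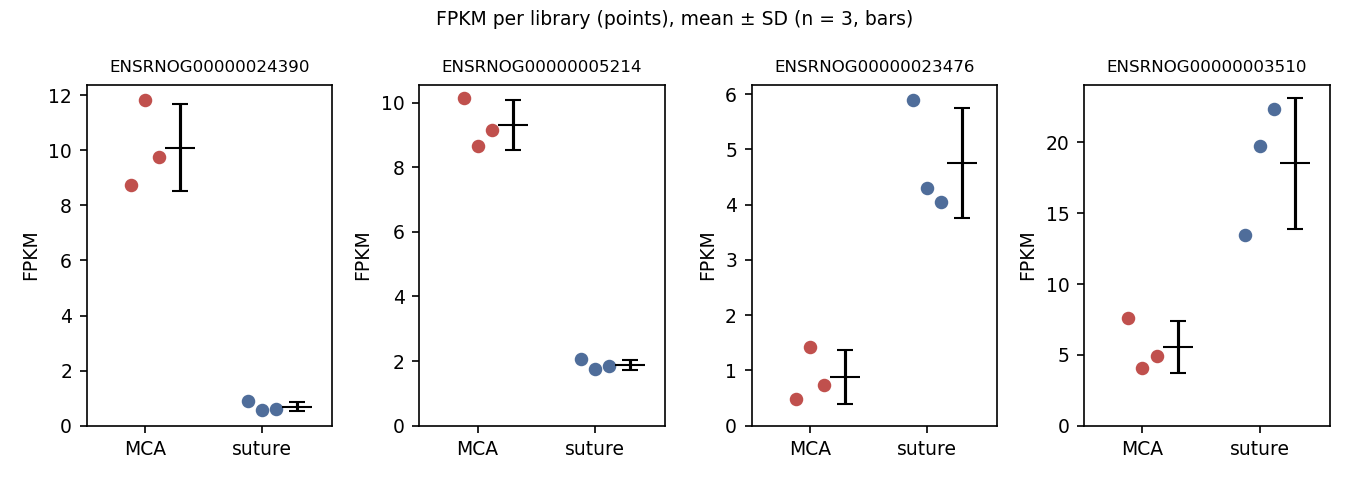
FPKM of the 4 genes given by identifier (vertical axes, starting at 0), with one point per library, MCA in red and suture in blue, and bars for the mean ± SD (n = 3). The first pair of genes is higher and the second pair lower in the MCA libraries, with no overlap.

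The precision of the comparison set which differences could be seen. The 95% interval of the log2 fold had a median half-width of 0.71 log2 units. It lay within 1 log2 unit of 0, and so excluded a 2-fold difference on this scale, for 7312 genes, 53.8% of those tested. For the other 6279 genes a 2-fold difference in at least one direction was not excluded. The median half-width was 0.72 log2 units for the 4362 genes with a mean of 1 to 5 FPKM, a class whose spread the pseudocount compresses. It was 0.66 for the 5341 genes at 5 to 20 FPKM, 0.73 for the 3209 genes at 20 to 100 FPKM and 0.98 for the 679 genes at 100 FPKM or more. Intervals excluded a 2-fold difference for 48.1%, 59.5%, 57.1% and 30.2% of the genes in these classes. In simulated data of this design, 2.31% of genes shifted by 1 unit of log2(FPKM + 1) and 81.5% of genes shifted by 3 units passed the adjusted threshold. Simulated libraries were equally variable, and such a shift is a larger fold in FPKM for low genes. Downward shifts had no lower bound, so for low genes part of this recovery is of decreases that FPKM cannot show.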

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

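Chosen after seeing the data were limma-voom on recovered fragments, leaving out the 10 most abundant genes, and leaving out libraries in the similarity comparison. In 19 of 20 alternative settings 0 genes passed the adjusted threshold, with a smallest adjusted p between 0.0626 and 0.415. The exception was array weights, with 35 genes (34 higher and 1 lower with MCA), 1360 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0084. The weights ran from 0.290 for MCA replicate 2 to 4.31 for MCA replicate 1, estimated from the same libraries. The count at an unadjusted p under 0.05, 667 in the main test, stayed within 1.5 times in 16 settings. It was 334 with a filter at a mean of 5 FPKM, where 9229 genes were tested, and 511 to 1065 when 1 library was left out, with the 1065 reached without MCA replicate 2. With the replicate number as a block it was 1141 (597 higher and 544 lower with MCA), with 0 genes past the adjusted threshold. The numbers were not treated as pairs because the labels do not say that they pair animals. Deviations of same-numbered libraries from their group means correlated at 0.42, 0.53 and -0.0016. Those of different-numbered libraries correlated at -0.47 to 0.28, and MCA replicate 3 correlated best with suture replicate 1. With 3 libraries per group these values cannot settle whether the numbers pair animals. Among genes at least 2-fold apart at an unadjusted p under 0.05, the share higher with MCA was 70.6% in the main test and 67.0% to 70.6% under other scalings, but 42.2% without suture replicate 1, 54.9% without MCA replicate 1 and 86.4% without suture replicate 3. The median log2 fold of all genes moved between -0.08 and 0.07. Under array weights 3 of the 4 genes given by identifier passed the threshold: ENSRNOG00000024390 (adjusted p = 0.0084, 0.0084 to 0.415 over all settings run), ENSRNOG00000005214 (0.0139, 0.0139 to 0.415) and ENSRNOG00000023476 (0.0282, 0.0282 to 0.622, not tested at a mean of 5 FPKM). The 4 genes had been picked by small p in the same libraries, so their passing adds no independent support. The within-group minus between-group correlation ranged from -0.0096 to 0.029, the extremes coming without suture replicate 3 and without MCA replicate 1. Pseudocounts and scalings that keep the order of genes cannot move this rank measure. The alternatives fixed for the gene lists and the 20 healing genes were not run, since no identifier had a symbol. How far depth limits the calls was not tested apart from the spread between animals.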

Other observations

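The test on the 7 most abundant genes, the rescaling without the 10 most abundant genes, the shares without a pseudocount and the counts over the next 50 genes were chosen after the data had been seen. Over all of the next 50 genes by abundance, the ratio of the highest to the lowest library of a group had a median of 2.52 in the MCA group and 1.80 in the suture group. It exceeded 2 for 33 of the 50 genes with MCA and for 19 with suture. Between MCA replicates 1 and 3 alone the median ratio was 1.48, with 17 genes above 2, and between pairs of suture libraries it was 1.42 to 1.70, with 6 to 19 genes above 2. Of the 50 genes, 20 were highest in MCA replicate 3, 15 in MCA replicate 2, 8 in suture replicate 1, 3 each in MCA replicate 1 and suture replicate 3, and 1 in suture replicate 2. MCA replicate 2 was lowest for 19.

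MCA replicate 2 stood apart from its group. It lay over 2-fold from both other MCA libraries in 2129 of 13591 genes on the log2(FPKM + 1) scale, 539 higher and 1590 lower, against 140 to 959 genes for each of the other 5 libraries when set against both libraries of its own group. Counting error from its lower total needs the share of such genes to shrink with abundance. It also needs the share to be under 1% at a mean of at least 50 FPKM, but the share there was 29.8%. Each of the other 5 libraries also exceeded 1% there, with 1.17% to 8.91%, so this bar alone did not single out MCA replicate 2. Without a pseudocount the share for MCA replicate 2 was 23.6% of genes at 1 to 5 FPKM, 18.3% at 5 to 20, 19.5% at 20 to 50 and 30.3% at 50 FPKM or more. This share rose with abundance from 5 FPKM up but not from the lowest class. In the highest class the genes apart without a pseudocount had a median of 1039 fragments in this library. A few genes taking most of the counts would shift the rest together. The 10 most abundant genes of each library held 35.5% of FPKM in MCA replicate 2, 35.4% in MCA replicate 3 and 22.3% in MCA replicate 1. Their share did not set replicate 2 apart from replicate 3, so leaving such genes out was a weak test. Without the 10 genes highest on average and after rescaling, 2073 genes were still over 2-fold apart. These were 881 higher and 1192 lower, so the directions became more even but the count hardly moved. A different mix of bowel wall layers or cell types in the excised piece may explain such opposite shifts; it was not tested, since no gene could be named, and the design gives no biological difference within a group to test.

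The 7 most abundant genes moved almost in parallel. The median over their 21 pairs of the SD of the log2 ratio across the 6 libraries was 0.115, against a median of 1.12 and a 5th percentile of 0.697 for 10000 random draws of 7 from the next 50 genes by abundance. This is consistent with one shared source for these transcripts, whose share ran from 18.7% to 37.3% of total FPKM across libraries of both groups. Mitochondrially encoded transcripts are a candidate source, which was not tested. No identifier could be named, and the recovered lengths of the 7 genes were not compared with those of mitochondrial genes. The reference table used here holds 0 Ensembl identifiers and 0 genes of the mitochondrial chromosome.

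Genes at least 2-fold apart at an unadjusted limma p under 0.05 were more often higher than lower with MCA, 247 against 103. Scaling between libraries did not account for this: the lowest share higher under the scalings tried was 67.0%. The share depended on single libraries, falling to 42.2% without suture replicate 1, so one library could decide it. Of the 10 splits of the 6 libraries, 6 gave as uneven a share as the real one (70.6% in the real split, and up to 94.9% in the others), and 10 splits are too few for a share under 0.05.

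The gene counts were set against the same splits, which are again too few for a share under 0.05. For genes past the adjusted threshold the comparison says nothing, since a real count of 0 is matched by all 10 splits by construction (at most 1 gene in the others). At an unadjusted p under 0.05, 4 of the 10 gave at least as many genes as the real split (667, against at most 2427 in the others). The split with 2427 genes set MCA replicates 1 and 3 and suture replicate 1 against the rest, the order of the libraries on the first principal component, which is computed from the same values. It was singled out as the highest of the splits, and 1 gene passed the adjusted threshold in it. The real split nonetheless gave the second lowest smallest adjusted p of the 10, 0.0632, after 0.0182 in that split.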
